A study of Homo sapiens with 56 samples.

How the data were processed

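RNA was measured by sequencing in 7 established human colorectal cancer cell lines, each treated with 10 mM 2-methylisocitrate (2-MiCit) or with its vehicle, water. There were 4 libraries in each of the 14 groups, 56 in all. Total RNA was extracted with a GenElute column kit and libraries were made with the Illumina Stranded mRNA Prep kit, per the labels' protocols. The growth protocol in the labels names 4 of the lines (HCT116, DLD1, LoVo and SW948), and the length of treatment is not given in the sources used here. The labels number the libraries 1 to 4 within each group and do not say whether they came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

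The authors deposited 2 tables of raw counts per gene, one for HCT116, DLD1, LoVo and SW948 (16485 genes, 32 libraries) and one for HT29, SKCO1 and SW1417 (16454 genes, 24 libraries). They also deposited a table of normalized counts for each, a signal on a linear scale that was used here only to recover the authors' scaling. Per the submitters' processing notes, the tools were bcl2fastq 2.20.0, Trimmomatic 0.39, Salmon 1.5.0 and DESeq2, with the GRCh38.p13 build. The deposited raw counts are whole numbers. Salmon assigns reads to transcripts and shares those that match several, so genes with near-identical copies, pseudogenes and readthrough genes are uncertain. In the first table the authors' normalized counts were the raw counts divided by a single factor per library. In the last table the ratio of raw to normalized count differed from gene to gene within a library, with its 99th percentile between 1.896 and 2.135 times its 1st among genes with at least 50 counts.

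Library totals ran from 13.8 to 19.4 M counts in the first table and from 29.1 to 45.4 M in the last. The lines of the last table were therefore measured with smaller counting error. Gene identifiers were matched to GENCODE release 29 (GRCh38) for symbols, coordinates and transcript lengths. Of the identifiers, 1140 in the first table and 1162 in the last had no match, and they held 3.29% to 4.45% of a library's counts. They stayed in the library sizes and tests but are not named.

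Each line was tested alone, 2-MiCit against control, with edgeR 4.0.16 in R 4.3.3: genes were filtered with filterByExpr, scaled with TMM factors and tested two-sided with the robust quasi-likelihood F test. A gene was called at a Benjamini-Hochberg adjusted p below 0.05, and each adjusted p of a gene below is from this test unless another is named. Fold changes are 2-MiCit over control, standard errors (SE) come from the same fit, and levels are CPM (counts scaled to the library size) with the TMM factors. Whether the effect of 2-MiCit differed between lines was tested with the treatment-by-line interaction terms of 1 edgeR fit per table. Lines of different tables were not tested against each other.

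The design, tests, alternatives, gene lists and rule for naming genes were fixed before the data were examined. There were 34 gene lists, 4 of them markers of other cell types (fibroblast, leukocyte, endothelial and neural). The other lists cover cholesterol synthesis and uptake, fatty acid synthesis, amino acid and integrated stress response (ATF4), unfolded protein response, heat shock proteins, hypoxia, glycolysis, the tricarboxylic acid cycle, citrate transport, propionate metabolism, nuclear and mitochondrial genes of the respiratory chain, DNA replication, mitosis, p53 targets, homologous recombination and Fanconi genes, nucleotide synthesis, the NRF2 oxidative stress response, iron handling, metallothioneins, NF-kappaB and chemokines, interferon response, immediate early genes, intestinal differentiation, Wnt targets and stem cell genes, mesenchymal genes, ribosome biogenesis, ribosomal proteins, lysosome and autophagy, and replication-dependent histones. Lists with at least 5 tested members were tested with camera in limma 3.58.1, which asks whether a list moved relative to the other genes, with a preset correlation between genes of 0.01 and adjustment over the lists of a line. The test was repeated with an estimated correlation, and fry, which asks whether a list moves on balance one way, was run beside it.

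Genes with a symbol were named by rule. Per line, these were the 8 higher and the 8 lower called genes with the largest change, at least 5 CPM in the higher group and all 4 libraries of one group above all 4 of the other. Shared genes were the 10 higher and 10 lower genes called in one direction in the most lines and never in the other. For each called list, up to 4 members called in its direction were taken, smallest p first, and 2 members of an uncalled list. For each table, up to 8 genes called in opposite directions in different lines were taken by the interaction p. A further 12 genes of drug metabolism, citrate and isocitrate metabolism and p53 were named in every line where tested. A few genes that this rule names are not reported here.

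Each fit was tested on simulated counts with 200 changed genes. Of the genes changed 1.5-fold, the test recovered 76.1% in HCT116, 31.3% in DLD1, 77.6% in LoVo, 50.8% in SW948, 88.1% in HT29, 95.5% in SKCO1 and 98.5% in SW1417. At 2-fold it recovered between 84.9% (SW948) and 100% (SW1417). False calls were 1.08% (SW948) to 10.1% (SKCO1) of the calls, above the nominal share in HCT116 (9.63%), DLD1 (8.89%), LoVo (5.59%), HT29 (7.1%) and SKCO1.

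The alternatives were DESeq2's size factors, the authors' size factors (first table), no filter and a stricter filter (5 CPM in 4 libraries), DESeq2 1.42.0 as the test, the replicate number as a block, 1 fit over all lines of a table, the 2 other list tests and leaving out each library. Alternatives added after the data were seen were the authors' gene and library factors as offsets (last table), removal of each library's linear trend with transcript length, and the counts of genes called in at least 4 lines. In HCT116 all 4 same-numbered pairs of libraries deviated together from their group means (correlations across genes from 0.27 to 0.53, all over 0.1), so the numbers pair its libraries by the data, though the labels state no shared batch. No pair of same-group libraries agreed within sampling noise: the chi-square per gene was 4.12 to 84 over 84 pairs.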

Results

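The series asked how 2-methylisocitrate, an intermediate of the bacterial methylcitrate cycle that breaks down propionate, acts on colorectal cancer cells, in a study of how a microbial metabolite modulates chemotherapy. Gene expression was measured by RNA sequencing in the human colorectal cancer lines HCT116, DLD1, LoVo, SW948, HT29, SKCO1 and SW1417, with 10 mM 2-MiCit or water, in 4 libraries per group. No library received a chemotherapy drug according to the labels. The median library total was 15.9 M counts in HCT116, 15.5 M in DLD1, 15.1 M in LoVo, 15.3 M in SW948, 32.6 M in HT29, 38 M in SKCO1 and 39.2 M in SW1417.

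The number of genes called with 2-MiCit differed between lines. At an adjusted p below 0.05, 2635 genes were higher and 2489 lower in HCT116, 20 and 0 in DLD1, 218 and 96 in LoVo, 0 and 0 in SW948, 646 and 419 in HT29, 1187 and 1589 in SKCO1, and 414 and 570 in SW1417. Over 2-fold, 226 called genes were higher and 29 lower in HCT116, 8 and 0 in DLD1 by edgeR, 8 and 0 in LoVo, 34 and 7 in HT29, 18 and 0 in SKCO1, and 5 and 3 in SW1417. The median absolute log2 fold change of the called genes was 0.38 in HCT116, 0.89 in DLD1, 0.37 in LoVo, 0.27 in HT29, 0.15 in SKCO1 and 0.15 in SW1417. The counts and this median depend on how small a change the spread and depth of each line let the test call, and do not by themselves rank the lines by response. Of genes given a simulated 1.5-fold change, the test recovered 31.3% in DLD1 and 98.5% in SW1417. It recovered 76.1% in HCT116 and 77.6% in LoVo, so this recovery does not account for their difference in called genes (5124 against 314). Lines of different tables were not tested against each other. As a list, genes of mitosis were called lower in 6 lines. Those of DNA replication, nucleotide synthesis, ribosome biogenesis, heat shock, glycolysis, homologous recombination and the nuclear respiratory chain were called lower in 5. The nuclear respiratory chain was called higher in SW948. With an estimated correlation, mitosis kept its call in SW1417 alone (adjusted p = 0.0291) and DNA replication in HCT116 and SKCO1 (adjusted p = 0.00998 and 0.0435). Ribosome biogenesis kept its call in the same 2 lines (adjusted p = 0.00998 and 0.00592 with an estimated correlation). Nucleotide synthesis kept its call in HCT116 (adjusted p = 0.00998) and heat shock in SKCO1 (adjusted p = 0.0435). Homologous recombination, nuclear respiratory genes and glycolysis kept theirs in no line (smallest adjusted p for glycolysis = 0.142 with an estimated correlation). The larger counts of called genes in SKCO1 than in LoVo go with deeper libraries and a smaller spread (biological coefficient of variation 0.074 against 0.11).

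**Figure D1:**
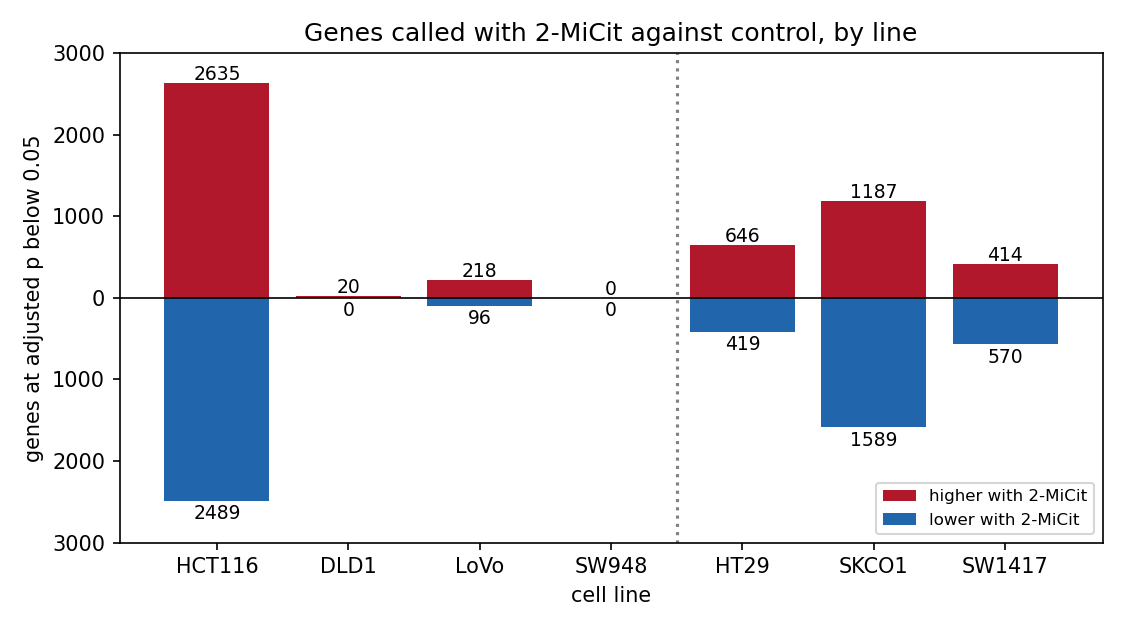
Number of genes called at an adjusted p below 0.05 with 2-MiCit against control, by cell line (4 libraries per group); bars above 0 are genes higher and bars below 0 genes lower with 2-MiCit, and the dotted line parts the lines of the first count table from those of the last. HCT116 had 2635 higher and 2489 lower genes and SW948 had none.

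In HCT116, 2-MiCit changed 5124 of 13834 tested genes, 37%. TAGLN, an actin-binding protein of smooth muscle and mesenchymal cells (ENSG00000149591, chromosome 11, 117199321 to 117204782, GRCh38), rose 4.21-fold (adjusted p = 5.41e-05). LOXL4, a collagen and elastin cross-linking enzyme (ENSG00000138131, chromosome 10, 98247690 to 98268250), rose 4.1-fold (adjusted p = 1.51e-06). ABCC3, an organic anion export pump (ENSG00000108846, chromosome 17, 50634777 to 50692252), rose 3.86-fold, from 11.4 ± 2.07 to 43.8 ± 5.38 CPM (SD, n = 4 per group; adjusted p = 1.31e-05), and CHAC1, which degrades glutathione, rose 3.44-fold (adjusted p = 1.51e-05). ANKRD2, CSTA, ST6GALNAC2 and MYO15B rose between 3.17- and 3.31-fold. Among genes that meet the naming rule (a symbol, at least 5 CPM in the higher group, no overlap of the groups), the largest falls were in CLK2, a kinase of splicing factors (2.97-fold, adjusted p = 0.000673), the chaperone cofactor SDF2L1 (2.05-fold, from 86.5 ± 8.49 to 42.2 ± 6.28 CPM), HGH1 (1.83-fold), PUF60 (1.87-fold) and CYB561D2 (1.82-fold). SENP3-EIF4A1 is a readthrough gene, SBDSP1 a pseudogene and ATAD3B a member of a family of near-identical copies, so their falls of 2.4-, 1.89- and 1.89-fold are uncertain.

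Amino acid and p53 genes rose in HCT116. Of 22 tested members of the ATF4 list, which serves amino acid supply and the integrated stress response, 19 rose and 1 fell (19 and 1 adjusted over the list alone; list adjusted p = 1.55e-10, adjusted p = 0.0739 with an estimated correlation). ASNS, asparagine synthetase, rose by 1.57 ± 0.05 on the log2 scale (SE; adjusted p = 1.29e-07), PSAT1 and PHGDH of serine synthesis by 1.09 ± 0.05 and 1.04 ± 0.08. Of 23 p53 targets, 17 rose and 0 fell by edgeR (17 and 0 adjusted over the list alone; list adjusted p = 7.17e-09, adjusted p = 0.0176 with an estimated correlation). They included the cell cycle inhibitor CDKN1A (log2 fold change 0.80 ± 0.07, adjusted p = 2.84e-05) and TP53INP1 (1.24 ± 0.08, adjusted p = 1.31e-05). Of 10 mesenchymal genes, 6 rose and 1 fell (6 and 1 adjusted over the list alone; list adjusted p = 0.0029, adjusted p = 0.0739 with an estimated correlation), including ACTA2 (1.63 ± 0.14) and CCN2 (0.87 ± 0.08). Interferon genes were called higher (8 of 16 rose, 9 adjusted over the list alone; list adjusted p = 0.0192, adjusted p = 0.251 with an estimated correlation). NF-kappaB genes and chemokines were higher (3 of 8 rose, 3 adjusted over the list alone; list adjusted p = 0.00646, adjusted p = 0.251 with an estimated correlation). So were mitochondrially encoded respiratory genes (4 of 13 rose, 4 adjusted over the list alone; list adjusted p = 0.0146, adjusted p = 0.525 with an estimated correlation). The mitochondrial call was lost without 2-MiCit replicate 1 or control replicate 4 (adjusted p = 0.0601 and 0.0501), and the interferon call with the stricter filter (adjusted p = 0.0601). With the replicate number as a block, the NRF2 list, with an adjusted p of 0.0596 without it, was called higher (adjusted p = 0.0449), and MT-ND5 lost its call (adjusted p = 0.0684 in place of 0.0165).

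Of 34 DNA replication genes in HCT116, 29 fell and 1 rose (30 and 1 adjusted over the list alone; list adjusted p = 2.03e-11, adjusted p = 0.00998 with an estimated correlation), among them RFC5 (log2 fold change -0.59 ± 0.04) and MCM7 (-0.43 ± 0.04). Of 28 nucleotide synthesis genes, 21 fell (22 fell and 1 rose adjusted over the list alone; list adjusted p = 7.17e-09, adjusted p = 0.00998 with an estimated correlation), with RRM2 at -0.59 ± 0.04 and PFAS at -0.74 ± 0.07. Of 21 ribosome biogenesis genes, 17 fell (19 adjusted over the list alone; list adjusted p = 1.05e-10, adjusted p = 0.00998 with an estimated correlation), with NCL at -0.67 ± 0.05 and NPM1 at -0.65 ± 0.05. All 9 heat shock genes fell (9 adjusted over the list alone; list adjusted p = 6.89e-07, adjusted p = 0.0766 with an estimated correlation), with HSPA8 at -0.80 ± 0.05. Of 27 mitosis genes, 16 fell (16 adjusted over the list alone; list adjusted p = 5.56e-07, adjusted p = 0.0745 with an estimated correlation), with CDC20 at -0.69 ± 0.05. In the unfolded protein response, 8 of 14 members fell and 1 rose (8 and 1 adjusted over the list alone; list adjusted p = 0.000841, adjusted p = 0.234 with an estimated correlation), the fallers including the endoplasmic reticulum chaperones HSPA5 (-0.64 ± 0.05) and HSP90B1 (-0.60 ± 0.05). Cholesterol genes were called lower (16 of 24 fell and 1 rose, 18 and 1 adjusted over the list alone; list adjusted p = 3.52e-06, adjusted p = 0.134 with an estimated correlation). Glycolysis genes were lower (10 of 15 fell, 10 adjusted over the list alone; list adjusted p = 8.98e-05, adjusted p = 0.142 with an estimated correlation). Homologous recombination genes were lower (10 of 19 fell, 10 adjusted over the list alone; list adjusted p = 0.00565, adjusted p = 0.375 with an estimated correlation). So were nuclear respiratory genes (13 of 42 fell, 12 adjusted over the list alone; list adjusted p = 8.2e-06, adjusted p = 0.483 with an estimated correlation). Ribosomal proteins were lower too (11 of 27 fell, 14 adjusted over the list alone; list adjusted p = 1e-05, adjusted p = 0.483 with an estimated correlation).

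In DLD1, 20 genes rose and none fell by edgeR, against 1227 higher and 1171 lower genes at an unadjusted p below 0.05, and 324 higher and 150 lower by DESeq2. The stricter filter gave 40 higher, 1 fit over 4 lines 733 and 619, and length trend removal 110 and 5. The replicate block gave 0 higher. The stress transcription factor ATF3 (ENSG00000162772, chromosome 1, 212565334 to 212620777) rose 3.38-fold, from 19.4 ± 1.49 to 65.5 ± 6.28 CPM (SD, n = 4 per group; adjusted p = 0.000324). DDIT4, an inhibitor of mTORC1 signalling (ENSG00000168209, chromosome 10, 72273920 to 72276036), rose 3.28-fold, from 34.2 ± 12.8 to 112 ± 21.2 CPM (adjusted p = 0.0472). NEDD9, NR1D1, KLHL24, CCNG2, DUSP5 and the amino acid transporter SLC38A2 rose between 2.03- and 2.29-fold. ATF3 kept its call without any single library (highest adjusted p = 0.00536) but not with the block (0.164). The other 7 lost theirs without some library (highest adjusted p = 0.258). The counts rested on single libraries: without control replicate 1 there were 163 higher and 20 lower genes. Without 2-MiCit replicate 1, control replicate 2, 2-MiCit replicate 2, control replicate 3, 2-MiCit replicate 3, control replicate 4 and 2-MiCit replicate 4 there were 10, 1, 1, 6, 2, 1 and 12 higher genes and 0 lower.

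As a list, ATF4 genes were higher in DLD1: 3 of 21 members rose, 10 adjusted over the list alone (list adjusted p = 1.17e-11, adjusted p = 0.143 with an estimated correlation). The risers were ATF3, DDIT4 and PPP1R15A (log2 fold change 0.87 ± 0.08, adjusted p = 0.0115). Immediate early genes were higher too, with 3 of 21 risen and 12 adjusted over the list alone (list adjusted p = 2.78e-09, adjusted p = 0.143 with an estimated correlation), including JUN (0.84 ± 0.10, adjusted p = 0.0194). PPP1R15A lost its call without 4 of the 8 libraries (highest adjusted p = 0.0734) and JUN without 5 (highest adjusted p = 0.109). The lists below were lower with no member called by edgeR. Heat shock proteins were lower (0 of 9, 4 adjusted over the list alone; list adjusted p = 7.51e-05, adjusted p = 0.123 with an estimated correlation). The unfolded protein response was lower (0 of 14, 7 adjusted over the list alone; list adjusted p = 0.00411, adjusted p = 0.301 with an estimated correlation). DNA replication was lower (0 of 34, 2 adjusted over the list alone; list adjusted p = 3.01e-06, adjusted p = 0.143 with an estimated correlation). Nucleotide synthesis was lower (0 of 27, 0 adjusted over the list alone; list adjusted p = 0.000202, adjusted p = 0.169 with an estimated correlation). So was ribosome biogenesis (0 of 21, 0 adjusted over the list alone; list adjusted p = 0.00772, adjusted p = 0.169 with an estimated correlation). Glycolysis (0 of 15, 0 adjusted over the list alone; list adjusted p = 0.0265, adjusted p = 0.301 with an estimated correlation) was called lower. Its call was lost without 2-MiCit replicate 2, control replicate 3 or control replicate 4 (adjusted p = 0.0504, 0.0855 and 0.0639). The tricarboxylic acid cycle (0 of 18, 0 adjusted over the list alone; list adjusted p = 0.0388, adjusted p = 0.344 with an estimated correlation) was called lower. Its call was lost without 2-MiCit replicate 1, control replicate 2, control replicate 4 or 2-MiCit replicate 4 (adjusted p = 0.0518, 0.0712, 0.0561 and 0.0722), and both lost theirs with the length trend removed (adjusted p = 0.104 for glycolysis and 0.719 for the cycle). Ribosomal proteins were lower (median log2 fold change -0.35 over 27 genes; 0 called, 0 adjusted over the list alone; list adjusted p = 3.49e-07, adjusted p = 0.508 with an estimated correlation). So were nuclear respiratory genes (-0.41 over 42 genes; 0 called, 0 adjusted over the list alone; list adjusted p = 1.08e-09, adjusted p = 0.473 with an estimated correlation). Transcripts of these 2 lists are short, and DLD1 control replicate 1 had the steepest length trend of any library: log2 CPM relative to the line's other libraries changed by -0.424 per doubling of transcript length. Without it, the median over both lists was -0.16 in place of -0.40, with both lists still lower (adjusted p = 3.18e-05 and 1.51e-08).

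In LoVo, 218 genes rose and 96 fell. The placental-type alkaline phosphatases ALPG (ENSG00000163286, chromosome 2, 232406843 to 232410714) and ALPP (chromosome 2, 232378534 to 232382889) rose 1.99- and 1.88-fold, ALPG from 87.2 ± 4.03 to 174 ± 7.71 CPM (SD, n = 4 per group; adjusted p = 9.92e-06). They are near-identical copies that can share reads. PCK1, the cytosolic enzyme that starts gluconeogenesis (ENSG00000124253, chromosome 20, 57561080 to 57568112), rose 2.16-fold, from 27.4 ± 4.34 to 59.5 ± 7.55 CPM (adjusted p = 0.00259). ANK1 rose 2.7-fold, CCDC92 2.47-fold, BDKRB2 1.97-fold, the lipase LIPH 1.9-fold and TP53INP1 1.86-fold. IFRD1 fell 1.41-fold (adjusted p = 0.00188), RGS2 1.49-fold, the peptide precursor NTS 1.73-fold, C5orf63 1.73-fold and AMN1 1.39-fold. NOTCH2NLC and HMGB1P5, which have near-identical copies, and the readthrough gene ISY1-RAB43 fell between 1.59- and 1.91-fold, with uncertainty.

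Most of the lists called in LoVo were lower. Ribosome biogenesis had 2 of 21 members fallen, 13 adjusted over the list alone (list adjusted p = 2.5e-07, adjusted p = 0.101 with an estimated correlation). Heat shock had 2 of 9, 7 adjusted over the list alone (list adjusted p = 8.1e-06, adjusted p = 0.101 with an estimated correlation). The unfolded protein response had 2 of 14, 8 adjusted over the list alone (list adjusted p = 8.1e-06, adjusted p = 0.101 with an estimated correlation), with HSPA5 at -0.28 ± 0.06. Cholesterol genes had 2 of 24 fallen, 10 adjusted over the list alone (list adjusted p = 4.03e-06, adjusted p = 0.101 with an estimated correlation), with INSIG1 at -0.43 ± 0.08. Nucleotide synthesis had 1 of 28, 10 fallen and 1 risen adjusted over the list alone (list adjusted p = 2.82e-05, adjusted p = 0.101 with an estimated correlation). Mitosis had 1 of 27, 5 adjusted over the list alone (list adjusted p = 0.000389, adjusted p = 0.101 with an estimated correlation). DNA replication was lower with no member called by edgeR (0 of 34, 0 adjusted over the list alone; list adjusted p = 8.1e-06, adjusted p = 0.239 with an estimated correlation). So were nuclear respiratory genes (0 of 41, 0 adjusted over the list alone; list adjusted p = 8.1e-06, adjusted p = 0.648 with an estimated correlation). The p53 targets were higher (3 of 24 rose, 4 adjusted over the list alone; list adjusted p = 0.0106, adjusted p = 0.101 with an estimated correlation). Interferon genes were higher (1 of 17 rose, 2 adjusted over the list alone; list adjusted p = 0.00653, adjusted p = 0.136 with an estimated correlation), the riser being MX1 (0.42 ± 0.06, adjusted p = 0.00661). The ATF4 list was lower, with ASNS and PSAT1 the 2 of 22 that fell and 6 fallen and 1 risen adjusted over the list alone (list adjusted p = 0.0286, adjusted p = 0.447 with an estimated correlation). It lost its call without control replicate 1, control replicate 2, 2-MiCit replicate 3 or 2-MiCit replicate 4 (adjusted p = 0.0859, 0.0694, 0.0867 and 0.0689) and with the length trend removed (adjusted p = 0.076). Glycolysis (0 of 15, 0 adjusted over the list alone; list adjusted p = 0.0191, adjusted p = 0.454 with an estimated correlation) was called lower. Its call was lost without 2-MiCit replicate 4 (adjusted p = 0.0689). Homologous recombination (0 of 19, 2 adjusted over the list alone; list adjusted p = 0.0288, adjusted p = 0.577 with an estimated correlation) was called lower. Its call was lost without control replicate 1, control replicate 2, 2-MiCit replicate 2 or 2-MiCit replicate 3 (adjusted p = 0.197, 0.0561, 0.0816 and 0.0636) and with the stricter filter (adjusted p = 0.0567).

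The counts in LoVo moved with the scaling and with single libraries. The authors' size factors gave 238 higher and 59 lower genes, removal of the length trend 372 and 296, and DESeq2 459 and 477. Without control replicate 1 there were 528 higher and 540 lower genes, without 2-MiCit replicate 1 there were 44 and 5, without control replicate 2 there were 50 and 8, and without 2-MiCit replicate 2 there were 35 and 4. Without control replicate 3 there were 32 and 4, without 2-MiCit replicate 3 there were 112 and 38, without control replicate 4 there were 200 lower, and without 2-MiCit replicate 4 there were 57 and 11. Of the 16 genes named for the size of their change, 9 kept their call without any single library, among them ALPG, ALPP, PCK1, ANK1, LIPH and IFRD1. Of the 23 calls of list members named by the rule, 22 were lost without some library (highest adjusted p = 0.167).

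In SW948, no gene was called by edgeR: the smallest adjusted p was 0.522, with 479 higher and 409 lower genes at an unadjusted p below 0.05, where chance alone gives about 667 of the 13334 tested. DESeq2 also called 0 and 0. Without 2-MiCit replicate 2, 1 gene was higher and 2 lower. As lists, ribosomal proteins were higher (median log2 fold change 0.30 over 27 genes; 0 called, 0 adjusted over the list alone; list adjusted p = 7.49e-07, adjusted p = 0.547 with an estimated correlation). So were nuclear respiratory genes (0.31 over 42 genes; 0 called, 0 adjusted over the list alone; list adjusted p = 1.18e-08, adjusted p = 0.544 with an estimated correlation), the reverse of DLD1. Here 2-MiCit replicate 2 had a length trend of -0.322 per doubling, and without it the median over both lists was 0.09 in place of 0.30, with both still higher (adjusted p = 1e-05 and 5.71e-06). Cholesterol genes were higher as well (0 of 24 called, 0 adjusted over the list alone; list adjusted p = 0.00134, adjusted p = 0.411 with an estimated correlation).

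The other 5 lists called in SW948 each lost their call without single libraries. Mitosis was lower (0 of 27, 0 adjusted over the list alone; list adjusted p = 0.0207, adjusted p = 0.411 with an estimated correlation), but not called without control replicate 2 or 2-MiCit replicate 3 (adjusted p = 0.0923 and 0.0804). Mitochondrially encoded respiratory genes were lower (0 of 13, 0 adjusted over the list alone; list adjusted p = 0.00722, adjusted p = 0.616 with an estimated correlation). It was not called without control replicate 1, 2-MiCit replicate 2 or 2-MiCit replicate 3 (adjusted p = 0.0886, 0.0641 and 0.231). Metallothioneins were lower (0 of 6, 0 adjusted over the list alone; list adjusted p = 0.0136, adjusted p = 0.411 with an estimated correlation). The call was lost without 2-MiCit replicate 1 or 2-MiCit replicate 3 (adjusted p = 0.0677 and 0.052). NRF2 genes were higher (0 of 19, 4 adjusted over the list alone; list adjusted p = 0.0254, adjusted p = 0.544 with an estimated correlation). That call ended without 2-MiCit replicate 1, control replicate 2, 2-MiCit replicate 3 or 2-MiCit replicate 4 (adjusted p = 0.0654, 0.117, 0.052 and 0.11) and with the length trend removed (adjusted p = 0.318). Histones were higher (0 of 7, 1 adjusted over the list alone; list adjusted p = 0.0342, adjusted p = 0.497 with an estimated correlation). It was not called without 2-MiCit replicate 1, 2-MiCit replicate 3 or control replicate 4 (adjusted p = 0.066, 0.143 and 0.138) and with the length trend removed (adjusted p = 0.591). Without 2-MiCit replicate 3, 3 lists were called in place of 8, and without 2-MiCit replicate 1 there were 5.

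**Figure D2:**
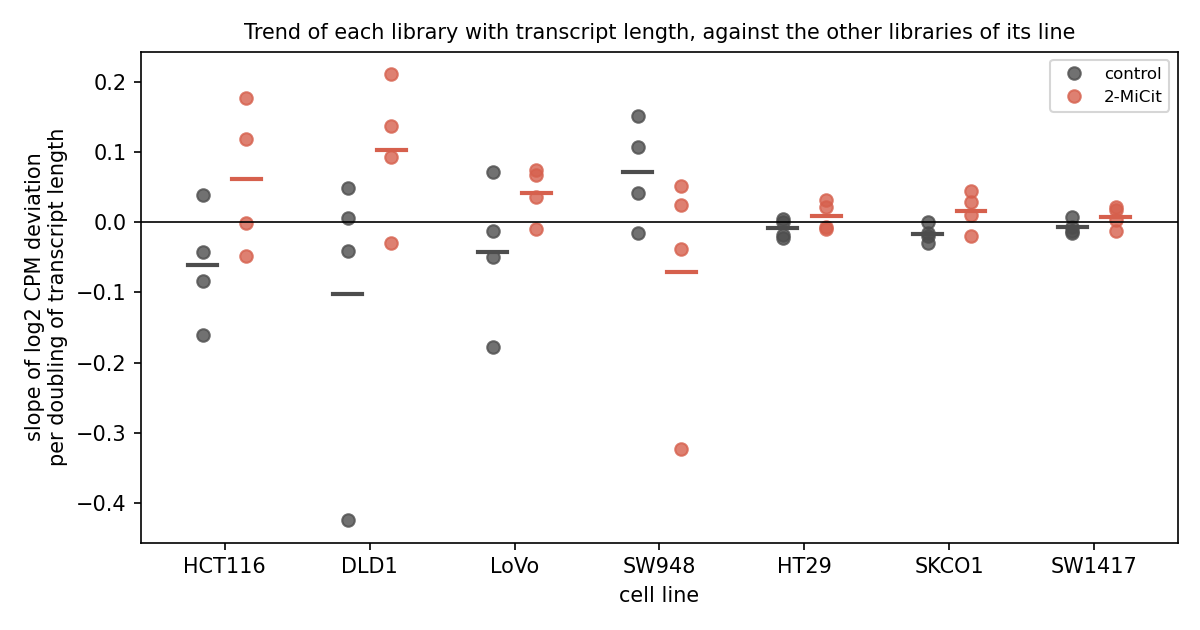
Change in log2 CPM, relative to the line's other libraries, per doubling of transcript length; each point is 1 library, bars are group means and the x axis gives the cell line, with control in grey and 2-MiCit in red. DLD1 control replicate 1 (-0.424) and SW948 2-MiCit replicate 2 (-0.322) lie lowest.

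In HT29, 646 genes rose and 419 fell. TXNIP, an arrestin family protein that limits glucose uptake (ENSG00000265972, chromosome 1, 145992435 to 145996600), rose 2.47-fold, from 136 ± 19.4 to 336 ± 37.1 CPM (SD, n = 4 per group; adjusted p = 0.00117). Its relative ARRDC4 (ENSG00000140450, chromosome 15, 97960698 to 97973838) rose 2.36-fold, from 10.7 ± 1.48 to 25.3 ± 1.76 CPM (adjusted p = 0.000127). FMO5, NEB, RASL11A, the prolactin receptor PRLR, the histone H2AC6 and PLA2G4F rose between 1.88- and 2.13-fold. ADAM19 fell 1.76-fold (adjusted p = 0.000494), the beta tubulin TUBB 1.4-fold from 1010 ± 27 to 720 ± 34.2 CPM (adjusted p = 0.000135), DHRS2 1.45-fold, and CDC20, HMMR, NTSR1 and C18orf54 between 1.36- and 1.37-fold. FAM72D, one of several near-identical copies, fell 1.43-fold with uncertainty, and lost its call without control replicate 3 (adjusted p = 0.0577).

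Mitosis genes stood out among the lists in HT29: 24 of 27 fell, 26 adjusted over the list alone (list adjusted p = 2.6e-24, adjusted p = 0.0588 with an estimated correlation), among them CCNB1 (log2 fold change -0.34 ± 0.04), TOP2A (-0.27 ± 0.03) and UBE2C (-0.40 ± 0.05). Cholesterol genes rose, 12 of 24 and 14 adjusted over the list alone (list adjusted p = 2.55e-10, adjusted p = 0.383 with an estimated correlation), with INSIG1 at 0.55 ± 0.06 and HMGCS1 at 0.41 ± 0.06. Of 13 intestinal differentiation genes, 4 rose and 1 fell (5 and 2 adjusted over the list alone; list adjusted p = 0.0108, adjusted p = 0.406 with an estimated correlation), including PHGR1 (0.88 ± 0.08) and the mucin MUC13 (0.49 ± 0.05). That list lost its call without 2-MiCit replicate 4 (adjusted p = 0.0554). Wnt and stem cell genes were higher (2 of 15 rose, 5 adjusted over the list alone; list adjusted p = 0.00541, adjusted p = 0.411 with an estimated correlation). Interferon genes were higher (1 of 18 rose, 5 adjusted over the list alone; list adjusted p = 0.0108, adjusted p = 0.24 with an estimated correlation). Ribosome biogenesis was lower (0 of 21, 0 adjusted over the list alone; list adjusted p = 7.86e-05, adjusted p = 0.383 with an estimated correlation). Fatty acid synthesis was higher (2 of 12 rose, 4 rose and 1 fell adjusted over the list alone; list adjusted p = 0.0248, adjusted p = 0.507 with an estimated correlation), with ACSS2 at 0.58 ± 0.06. The call was lost without control replicate 4 or 2-MiCit replicate 2 (adjusted p = 0.064 and 0.0622). Histones were higher (2 of 11 rose, 3 adjusted over the list alone; list adjusted p = 0.0143, adjusted p = 0.411 with an estimated correlation). That call ended without 2-MiCit replicate 1 (adjusted p = 0.0637). Homologous recombination was lower (1 of 19 fell, 3 adjusted over the list alone; list adjusted p = 0.0306, adjusted p = 0.813 with an estimated correlation). It was not called without control replicate 1, control replicate 2, 2-MiCit replicate 3 or 2-MiCit replicate 4 (adjusted p = 0.0724, 0.145, 0.0957 and 0.167). Without 2-MiCit replicate 2, 16 lists were called in place of 9.

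The counts of genes in HT29 were 323 and 175 without control replicate 1, 299 and 153 without control replicate 3, 353 and 179 without 2-MiCit replicate 3, and 345 and 231 without 2-MiCit replicate 4. The authors' gene and library factors as offsets gave 299 higher and 183 lower genes, DESeq2 gave 730 lower, and 1 fit over the 3 lines gave 1221 and 1270. Of the 38 calls of list members named by the rule in HT29, 13 were lost without some library (highest adjusted p = 0.15).

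In SKCO1, 1187 genes rose and 1589 fell, nearly all by less than 2-fold: 18 rose by more. MYH7B (ENSG00000078814, chromosome 20, 34975403 to 35002437) rose 1.88-fold, from 4.51 ± 0.348 to 8.49 ± 0.826 CPM (SD, n = 4 per group; adjusted p = 1.66e-05). SLC5A1, the sodium-glucose cotransporter of the intestinal brush border (ENSG00000100170, chromosome 22, 32043032 to 32113029), rose 1.67-fold, from 10.1 ± 0.279 to 16.8 ± 0.724 CPM (adjusted p = 1e-06). MUC16, the Wnt antagonist DKK4, CLIC3, the chemokine CCL24 and IGFL4 rose between 1.52- and 1.64-fold. ANKRD1, ZBED2, DLX1, KIAA1549L, PDE1C, RGS10 and the ecto-nucleotidase NT5E fell between 1.35- and 1.45-fold. PDE1C was at 0.02 on the log2 scale, with no fall, with the authors' gene and library factors as offsets (adjusted p = 0.969).

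Of 34 DNA replication genes in SKCO1, 24 fell, 29 adjusted over the list alone (list adjusted p = 1.38e-15, adjusted p = 0.0435 with an estimated correlation), with CDC6 at -0.18 ± 0.02 on the log2 scale. Of 21 ribosome biogenesis genes, 16 fell, 20 adjusted over the list alone (list adjusted p = 8.44e-13, adjusted p = 0.00592 with an estimated correlation), with NOP56 at -0.20 ± 0.02. Nucleotide synthesis (20 of 27 fell, 22 fell and 1 rose adjusted over the list alone; list adjusted p = 7.73e-12, adjusted p = 0.0875 with an estimated correlation) included RRM2 at -0.23 ± 0.02. Mitosis (18 of 27 fell, 19 adjusted over the list alone; list adjusted p = 9.81e-10, adjusted p = 0.088 with an estimated correlation) included UBE2C at -0.27 ± 0.03. Of 12 mesenchymal genes, 7 fell, 8 adjusted over the list alone (list adjusted p = 0.00012, adjusted p = 0.0435 with an estimated correlation), including CCN1 (-0.43 ± 0.05) and TGFBI (-0.23 ± 0.03). Of 21 immediate early genes, 9 fell and 1 rose (9 and 1 adjusted over the list alone; list adjusted p = 0.000788, adjusted p = 0.0466 with an estimated correlation), including FOSL1 (-0.35 ± 0.03). Of 10 heat shock genes, 7 fell, 9 adjusted over the list alone (list adjusted p = 6.72e-06, adjusted p = 0.0435 with an estimated correlation). Glycolysis fell (9 of 15, 9 adjusted over the list alone; list adjusted p = 1.77e-05, adjusted p = 0.263 with an estimated correlation), with ENO1 at -0.25 ± 0.03. The tricarboxylic acid cycle fell too (6 of 18, 9 adjusted over the list alone; list adjusted p = 0.000246, adjusted p = 0.33 with an estimated correlation), with citrate synthase CS at -0.18 ± 0.03. Homologous recombination was lower (6 of 19, 10 adjusted over the list alone; list adjusted p = 0.000119, adjusted p = 0.192 with an estimated correlation). Ribosomal proteins fell slightly (6 of 27, 7 adjusted over the list alone; list adjusted p = 0.00012, adjusted p = 0.537 with an estimated correlation). Nuclear respiratory genes (10 of 41, 10 adjusted over the list alone; list adjusted p = 0.000267, adjusted p = 0.465 with an estimated correlation) lost their call with the length trend removed (adjusted p = 0.107). Higher were Wnt and stem cell genes (7 of 15 rose and 2 fell, 8 and 2 adjusted over the list alone; list adjusted p = 0.000788, adjusted p = 0.23 with an estimated correlation), with NOTUM at 0.29 ± 0.03. Cholesterol genes were also higher (9 of 24 rose, 11 rose and 2 fell adjusted over the list alone; list adjusted p = 0.00451, adjusted p = 0.418 with an estimated correlation). So were mitochondrially encoded respiratory genes (0 of 13 by edgeR, 3 adjusted over the list alone; list adjusted p = 0.00114, adjusted p = 0.465 with an estimated correlation). The authors' gene and library factors as offsets gave 434 higher and 764 lower genes, and 1 fit over the 3 lines 626 and 1010. Of the 84 calls of list members named by the rule in SKCO1, 14 were lost without some library (highest adjusted p = 0.115).

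In SW1417, 414 genes rose and 570 fell, with 5 risen and 3 fallen by over 2-fold. ELAPOR1 (ENSG00000116299, chromosome 1, 109113679 to 109206781) rose 1.63-fold, from 17.1 ± 0.394 to 27.8 ± 0.529 CPM (SD, n = 4 per group; adjusted p = 2.3e-07). KLHL24, SLC3A1, BMX, WNK4, NOX1, ZNF490 and AKR1C2 rose between 1.42- and 1.48-fold; AKR1C2 has near-identical copies, and ZNF490 lost its call without 6 of the 8 libraries (highest adjusted p = 0.0765). The stress keratins KRT6A (ENSG00000205420, chromosome 12, 52487174 to 52493257) and KRT16 fell 1.87- and 1.73-fold, KRT6A from 7.43 ± 0.776 to 3.97 ± 0.207 CPM (adjusted p = 5.02e-05); both have near-identical copies. LBH (ENSG00000213626, chromosome 2, 30231369 to 30323730) fell 1.6-fold, from 69.4 ± 2.2 to 43.3 ± 1.89 CPM (adjusted p = 6.72e-08). The Wnt antagonist DKK1 fell 1.53-fold (adjusted p = 1.1e-06), and SDCBP2, GBP6, C4BPB and the histone H2BC9 fell between 1.47- and 1.67-fold.

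Of 27 mitosis genes in SW1417, 13 fell, 21 adjusted over the list alone (list adjusted p = 4e-13, adjusted p = 0.0291 with an estimated correlation), with CENPE at -0.16 ± 0.03 on the log2 scale. DNA replication was lower (7 of 34 fell, 16 fell and 1 rose adjusted over the list alone; list adjusted p = 1.48e-08, adjusted p = 0.212 with an estimated correlation). So was homologous recombination (5 of 19 fell, 7 adjusted over the list alone; list adjusted p = 3.02e-05, adjusted p = 0.212 with an estimated correlation). Nucleotide synthesis was lower (5 of 27 fell, 5 adjusted over the list alone; list adjusted p = 0.00325, adjusted p = 0.269 with an estimated correlation). Glycolysis (8 of 15 fell and 1 rose, 9 and 1 adjusted over the list alone; list adjusted p = 1.85e-06, adjusted p = 0.143 with an estimated correlation) had PGK1 at -0.20 ± 0.02. Hypoxia genes (5 of 19 fell, 6 adjusted over the list alone; list adjusted p = 4.48e-05, adjusted p = 0.122 with an estimated correlation) had PDK1, a kinase that restrains pyruvate dehydrogenase, at -0.47 ± 0.04. NF-kappaB genes and chemokines (5 of 14 fell, 8 adjusted over the list alone; list adjusted p = 9.12e-06, adjusted p = 0.181 with an estimated correlation) had CXCL8 at -0.42 ± 0.04. Interferon genes (3 of 15 fell, 3 adjusted over the list alone; list adjusted p = 0.00522, adjusted p = 0.187 with an estimated correlation) had OAS3 at -0.29 ± 0.05. Heat shock was lower (5 of 9 fell, 6 adjusted over the list alone; list adjusted p = 4.48e-05, adjusted p = 0.158 with an estimated correlation). So was the ATF4 list (3 of 23 fell, 4 adjusted over the list alone; list adjusted p = 0.00522, adjusted p = 0.143 with an estimated correlation), with ASNS at -0.18 ± 0.03. Higher were p53 targets (6 of 24 rose and 1 fell, 7 and 1 adjusted over the list alone; list adjusted p = 0.000108, adjusted p = 0.0548 with an estimated correlation), with BBC3 at 0.31 ± 0.04. Wnt and stem cell genes were higher (6 of 17 rose and 1 fell, 8 and 1 adjusted over the list alone; list adjusted p = 1.49e-05, adjusted p = 0.0769 with an estimated correlation), with the stem cell receptor LGR5 at 0.24 ± 0.03.

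Smaller list calls in SW1417 rested on single libraries. The unfolded protein response was lower (2 of 14 fell, 6 fell and 2 rose adjusted over the list alone; list adjusted p = 0.0284, adjusted p = 0.441 with an estimated correlation). The call was lost without control replicate 1, 2-MiCit replicate 1 or 2-MiCit replicate 2 (adjusted p = 0.095, 0.0742 and 0.058). Immediate early genes were lower (4 of 20 fell and 1 rose, 6 and 1 adjusted over the list alone; list adjusted p = 0.0117, adjusted p = 0.526 with an estimated correlation), with FOSL1 at -0.34 ± 0.04. That call ended without control replicate 2 or 2-MiCit replicate 4 (adjusted p = 0.051 and 0.0962). Nuclear respiratory genes were lower (3 of 41 fell, 3 adjusted over the list alone; list adjusted p = 0.0105, adjusted p = 0.521 with an estimated correlation). It was not called without 2-MiCit replicate 2 (adjusted p = 0.0646) and with the length trend removed (adjusted p = 0.153). Propionate metabolism was higher (1 of 10 rose, 1 adjusted over the list alone; list adjusted p = 0.0318, adjusted p = 0.215 with an estimated correlation). The call was lost without control replicate 4, 2-MiCit replicate 3 or 2-MiCit replicate 4 (adjusted p = 0.102, 0.0594 and 0.055). Ribosomal proteins were higher (median log2 fold change 0.03; 0 of 27 called, 0 adjusted over the list alone; list adjusted p = 0.00522, adjusted p = 0.521 with an estimated correlation). That call ended without control replicate 4 (adjusted p = 0.0581). The counts of genes were 231 higher and 367 lower without control replicate 1, 246 and 336 without control replicate 3, 231 and 372 without 2-MiCit replicate 1, 196 and 344 without 2-MiCit replicate 2 and 187 and 303 without 2-MiCit replicate 3. The authors' gene and library factors as offsets gave 71 and 127, and 1 fit over the 3 lines 211 and 227. Of the 69 calls of list members named by the rule in SW1417, 29 were lost without some library (highest adjusted p = 0.154).

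**Figure D3:**
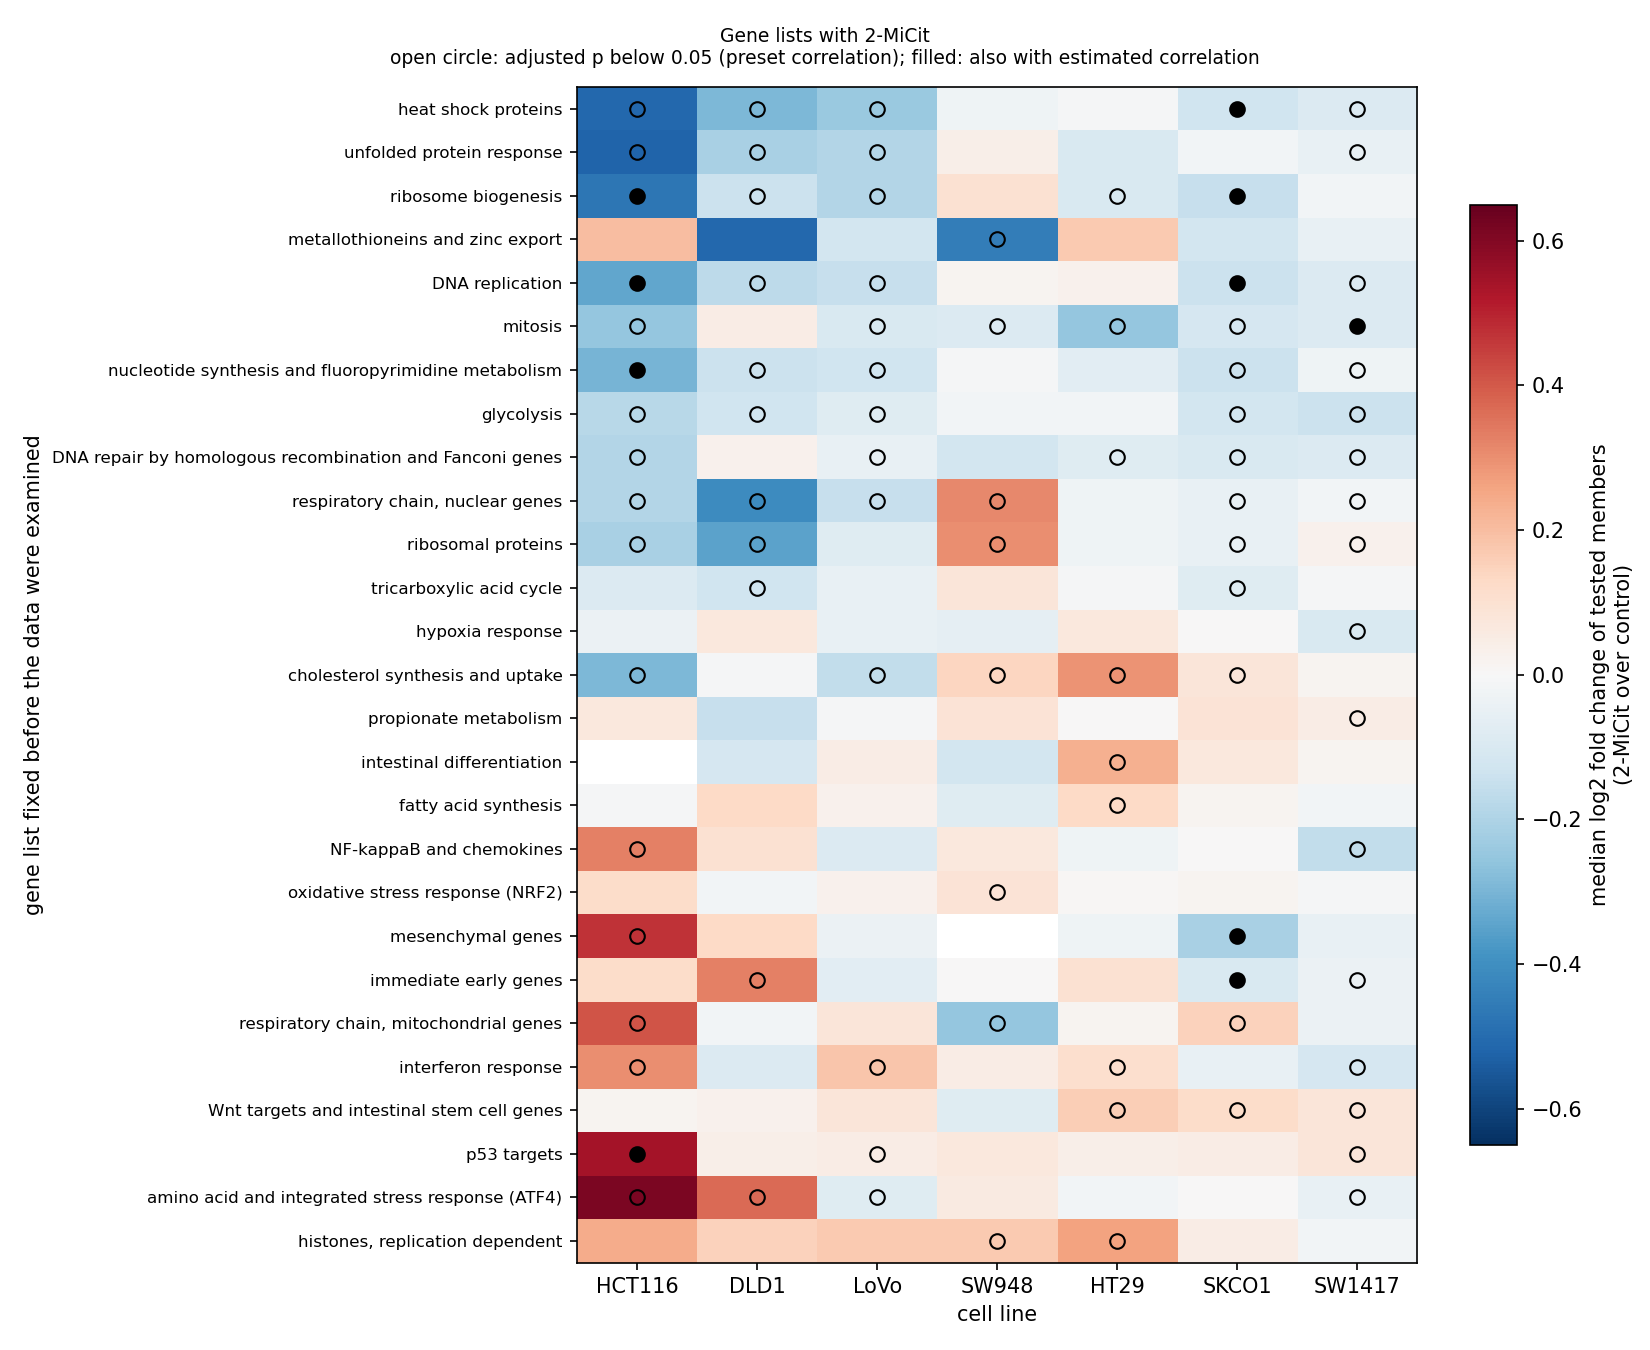
Median log2 fold change (2-MiCit over control) of the tested members of each gene list called in at least 1 line, by cell line; open circles mark lists called with the preset correlation, filled circles those also called with an estimated correlation, and blank squares lists with fewer than 5 tested members. Mitosis is lower in 6 of the 7 lines, while the ATF4 list is higher in HCT116 and DLD1 and lower in LoVo and SW1417.

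No gene was called in the same direction in all 7 lines, since edgeR called none in SW948 (479 higher and 409 lower there at an unadjusted p below 0.05, and 0 by DESeq2). KLHL24, a substrate adaptor of a ubiquitin ligase (ENSG00000114796, chromosome 3, 183635568 to 183684477), rose in 6 lines, by 0.25 (HT29) to 1.23 (HCT116) on the log2 scale. Its calls in DLD1, LoVo and HT29 were lost without 7, 4 and 7 of the 8 libraries (highest adjusted p = 0.231, 0.0741 and 0.0962). ARSD, CLIP2, ZNF219 and DPYSL2 rose in 5 lines, as did GTF2IP4, a pseudogene with near-identical copies, and H2AC6, MXD4, the mitochondrial kinase PINK1 and the cyclin CCNG2 rose in 4. CDC20, the activator of the anaphase-promoting complex (ENSG00000117399, chromosome 1, 43358955 to 43363203), fell in 5 lines, by 0.12 (SW1417) to 0.69 (HCT116) on the log2 scale; its calls in LoVo and SW1417 were lost without 6 and 4 libraries (highest adjusted p = 0.149 and 0.08). The proteasome subunit PSMD14, the DNA glycosylase TDG and the tropomyosin TPM3 also fell in 5 lines. The tubulins TUBA1C, TUBA1B and TUBB, which share near-identical sequence with other family members, the chaperonin HSPE1, ODC1 of polyamine synthesis and the proteasome subunit PSMB2 fell in 4. Of the calls of these shared genes, 2 of 2 in DLD1, 13 of 16 in LoVo, 7 of 15 in HT29, 6 of 18 in SW1417, 5 of 20 in SKCO1 and 0 of 20 in HCT116 were lost without some library (highest adjusted p = 0.231), so the numbers of lines rest partly on such calls.

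Over the 11319 genes tested in all lines, 43 were higher and 56 lower in at least 4 lines, where independent lists of the same sizes would share 0.367 and 0.702. These counts moved widely with the processing: 8 higher and 10 lower with the authors' factors, 76 and 215 with DESeq2, and 65 and 120 with the replicate block. The lower count was 102 with 1 fit over each table's lines and 98 with the length trend removed. As a count, the overlap of called genes was largest between HCT116 and SKCO1 in the lower direction. It was 892 genes against 293 expected (Fisher's exact test, adjusted p = 1.71e-295 over the pairs of lists), and 425 against 192 in the higher direction. HCT116 and LoVo shared 116 higher genes against 35 expected and 70 lower against 18. Relative to the expected number the lower overlap was 3.04 times for HCT116 and SKCO1 and 3.89 times for HCT116 and LoVo. The expected numbers and Fisher's test take genes as independent and equally easy to call. Genes that move together break this, so the p-value does not measure how well the lines repeat each other. Lines share no control libraries. The higher count of 43 was 25 without LoVo 2-MiCit replicate 1, 25 without LoVo control replicate 2, 24 without LoVo 2-MiCit replicate 2, 24 without LoVo control replicate 3. It was 27 without LoVo 2-MiCit replicate 4, 26 without HT29 control replicate 3, 28 without SW1417 control replicate 3, 26 without SW1417 2-MiCit replicate 2 and 26 without SW1417 2-MiCit replicate 3. The lower count of 56 was 117 without LoVo control replicate 1 and 35 without SW1417 2-MiCit replicate 3.

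The effect of 2-MiCit depended on the line. In the first 4 lines, 2837 of 15800 genes had an effect that differed between lines (edgeR interaction test), and in the last 3 lines 883 of 16090. With the replicate number as a block there were fewer in the first 4 lines, 1637, but more than 883 in the last 3. DESeq2 gave 4389 and 1454, and the authors' gene and library factors as offsets 308 in the last 3 lines. ASNS (ENSG00000070669, chromosome 7, 97852118 to 97872542) rose in HCT116 (log2 fold change 1.57 ± 0.05, SE) and fell in LoVo (-0.29 ± 0.05), with an interaction adjusted p of 4.8e-13, and PSAT1 likewise (1.09 ± 0.05 and -0.23 ± 0.05, interaction adjusted p = 5.75e-11). VSNL1 and HKDC1 also rose in HCT116 and fell in LoVo, and ABHD12B and TPTEP1 did the reverse. They are among the 7 genes called in opposite directions in the first table. Of the genes of the last table, 66 were called in opposite directions, 61 of them with a line-dependent effect. NT5E rose in HT29 (0.25 ± 0.04) and fell in SKCO1 (-0.46 ± 0.05, interaction adjusted p = 1.05e-06), as did the matrix protease MMP7 (0.37 ± 0.04 and -0.26 ± 0.08). The collagen receptor subunit ITGA2 and the glycosyltransferase GALNT5 rose in HT29 and fell in SW1417. MAB21L4 and PRR15L rose in HT29 and SKCO1 and fell in SW1417, and GPSM2 and PYCR1 of proline synthesis fell in HT29 and rose in SKCO1. The interaction calls of the named genes held without every single library. Of the single-line calls of the genes picked by the rule for opposite directions, 6 of 7 in LoVo, 4 of 8 in HT29, 2 of 7 in HCT116, 2 of 6 in SKCO1 and 0 of 4 in SW1417 were lost without some library, so many of the opposite calls rest on a call that single libraries end. Among them, those of ASNS and PSAT1 in LoVo were lost without 5 and 6 libraries (highest adjusted p = 0.0974 and 0.152), and that of MMP7 in SKCO1 without 5 (highest adjusted p = 0.119).

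By list, 19 of 23 ATF4 members, 18 of 24 p53 targets, 21 of 34 DNA replication genes, 15 of 21 ribosome biogenesis genes and 14 of 24 cholesterol genes had a line-dependent effect in the first 4 lines. In the last 3 lines, 13 of 27 mitosis genes did, 6 of 14 intestinal differentiation genes, 6 of 24 cholesterol genes and 0 of 24 ATF4 members (edgeR interaction test).

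**Figure D4:**
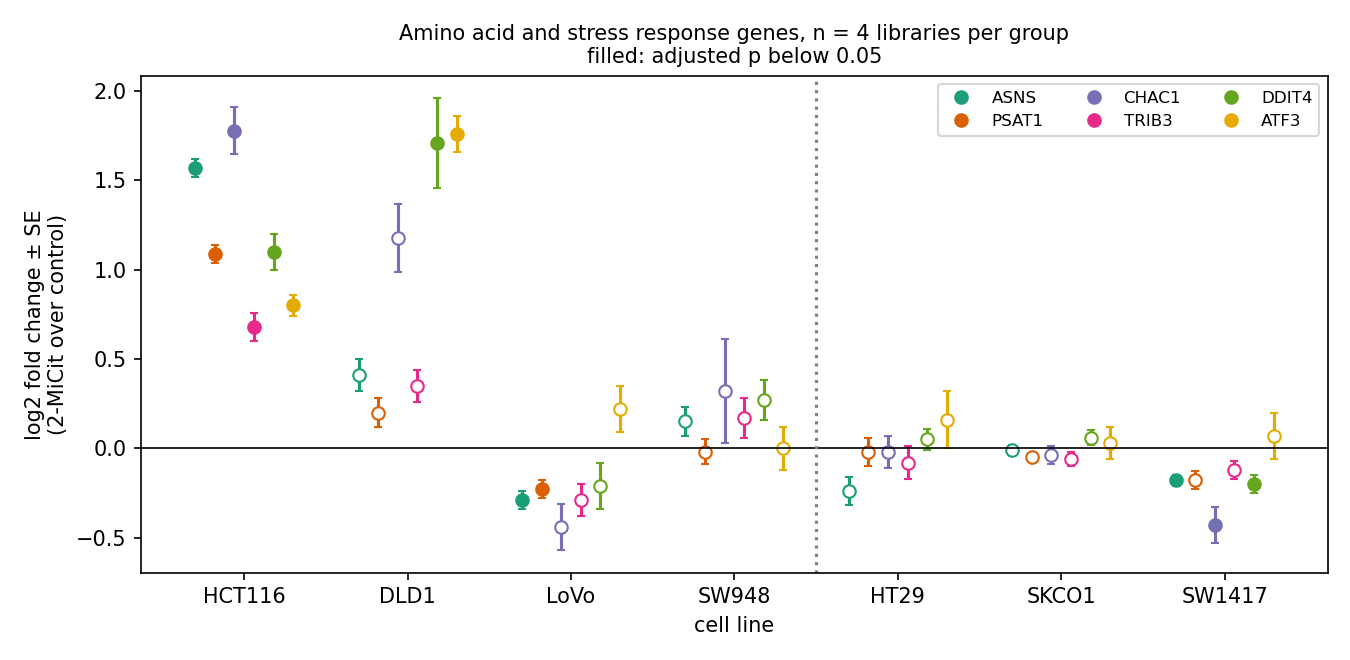
Log2 fold change (2-MiCit over control) of 6 genes of the ATF4 list by cell line, with bars of 1 standard error from the edgeR fit (4 libraries per group); filled points have an adjusted p below 0.05 and the dotted line parts the 2 count tables. ASNS is at 1.57 in HCT116 and -0.29 in LoVo, and ATF3 and DDIT4 are highest in DLD1.

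Among genes of fluoropyrimidine metabolism, thymidylate synthase TYMS (ENSG00000176890, chromosome 18, 657604 to 673578) fell in HCT116 (log2 fold change -0.39 ± 0.06, SE, adjusted p = 0.000753) and SKCO1 (-0.18 ± 0.03, adjusted p = 0.000262). Thymidine kinase TK1 (ENSG00000167900, chromosome 17, 78174075 to 78187233) fell in HCT116 (-0.33 ± 0.07), SKCO1 (-0.20 ± 0.04) and SW1417 (-0.20 ± 0.02). UMPS and TYMP fell in HCT116 (-0.36 ± 0.05 and -0.30 ± 0.08), TYMP losing its call without 2-MiCit replicate 2 or control replicate 3 (highest adjusted p = 0.0573), and UPP1 fell in SKCO1 (-0.30 ± 0.05). DPYD was called in none of the 3 lines where it was tested. Of the isocitrate dehydrogenase genes, IDH1 rose in SKCO1 (0.17 ± 0.03) and IDH3A fell in HCT116 (-0.34 ± 0.05). IDH2 rose in HCT116 (0.49 ± 0.08) and fell in SW1417 (-0.10 ± 0.03, a call lost without 7 of the 8 libraries, highest adjusted p = 0.119). CDKN1A (ENSG00000124762, chromosome 6, 36676460 to 36687339) rose in HCT116 and fell in SW1417 (-0.16 ± 0.03), and MDM2 rose in HCT116 (0.39 ± 0.08). The effect on CDKN1A depended on the line in the first table (interaction adjusted p = 7.65e-07) and in the last (0.0406).

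Lists of citrate transport, iron handling, and lysosome and autophagy were called by camera in none of the 7 lines (smallest adjusted p = 0.307 in SW948, 0.116 in HT29 and 0.0694 in HT29). By fry, citrate transport was called lower and iron handling higher in HCT116 (adjusted p = 0.0101 for each), and iron handling higher in HT29 (adjusted p = 0.0129). In HCT116, 2 of 5 citrate transport genes fell, 5 of 12 iron handling genes rose and 1 fell, and 6 of 21 lysosome and autophagy genes rose and 6 fell. Among markers of other cell types, those of fibroblasts and leukocytes stayed low. No gene of the fibroblast list passed 17.6 CPM (COL1A1, HCT116), and none of the leukocyte list 24.6 CPM (CD68, SKCO1). Some endothelial and neural markers were not low. The highest endothelial marker was ESAM in HT29 (59.3 CPM) and the highest neural marker TUBB3 in SKCO1 (336 CPM), genes that cancer lines can express themselves. The neural markers measured in SKCO1 had a median of 86.4 CPM in control. Of these 4 lists, 0 fibroblast markers were called in any line by edgeR. Summed over the lines, there were 0 higher and 3 lower calls of leukocyte markers, 1 and 1 of endothelial markers, and 1 and 3 of neural markers. The same gene can count in several lines: the 3 lower neural calls were all TUBB3, in HCT116, SKCO1 and SW1417.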

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

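The tests with the length trend removed from every library, of a single outlying library in SW948 and of sequencing depth were chosen only after the results they measure were seen.

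In 27 of 604 groups of 4 libraries of the named genes, 1 library stood apart by Dixon's ratio (the gap to its nearest neighbour over the group's range), where chance picks out about 1 group in 20, or 30 here. Those named below are not all of them. In HCT116 with 2-MiCit these were LOXL4 (0.855) and CYB561D2 (0.841). In DLD1 control it was IDH2 (0.881). In LoVo they were ANK1 (0.854), C5orf63 (0.87) and IDH1 (0.927) in control and HSPE1 (0.871) with 2-MiCit. In SW948 they were CDKN1A (0.846) in control and CCNG2 (0.901), HSPE1 (0.848) and UPP1 (0.89) with 2-MiCit. In HT29 they were MDM2 (0.834) in control and FMO5 (0.876), H2AC6 (0.88) and TK1 (0.946) with 2-MiCit. In SKCO1 they were ARSD (0.885), ZNF219 (0.879) and MDM2 (0.935) in control and KLHL24 (0.836), ARSD (0.841), TPM3 (0.874), HSPE1 (0.921) and TYMS (0.895) with 2-MiCit. In SW1417 they were NOX1 (0.843) in control and TUBB (0.854) with 2-MiCit. Of 28 groups tested on library totals and genes detected, 1 had such a library, the genes detected in LoVo with 2-MiCit (0.911).

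The effect of 2-MiCit differed between lines, by the interaction test, for 2837 genes in the first 4 lines and 883 in the last 3. Among the named genes with opposite calls, the interaction adjusted p was 4.8e-13 for ASNS, 5.75e-11 for PSAT1, 2.58e-06 for VSNL1, 0.000643 for HKDC1, 0.00448 for ABHD12B and 0.0131 for TPTEP1 in the first 4. In the last 3 it was 1.05e-06 for NT5E, 2.28e-06 for MAB21L4, 4.19e-06 for GPSM2, 5.84e-06 for GALNT5, 5.28e-05 for ITGA2, 5.48e-05 for PRR15L, 5.48e-05 for PYCR1 and 6.76e-05 for MMP7. Only the real one of 40 regroupings of the libraries within lines gave as many genes, in the first table (highest other 13) and in the last (highest other 3). The smallest share it could reach was 1 of 40, and regroupings that mix the treatments carry the treatment difference in their spread. They also did not keep the same-numbered pairs of HCT116. By itself the comparison therefore does not exclude chance for these counts.

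The ATF4 list was called higher in HCT116 and DLD1 and lower in LoVo and SW1417, and all 4 calls were lost with an estimated correlation (adjusted p = 0.0739, 0.143, 0.447 and 0.143 with an estimated correlation). DLD1 control replicate 1 alone does not account for the rise in DLD1: without it the list had an adjusted p of 1.1e-16, and ATF3, DDIT4 and PPP1R15A kept their calls (adjusted p = 3.63e-05, 0.00224 and 0.000453). The list's fall in LoVo lost its call without 4 of the libraries and with the length trends removed (adjusted p = 0.076), so it stays open. Of 23 members, 19 had a line-dependent effect in the first 4 lines and 20 with the length trends removed, so a length trend does not account for the difference between those lines. The count with the trends removed replaced an earlier test on the p-value of the list in HCT116 and DLD1, after its result was seen. A different response of the lines stays as a hypothesis, found and tested on the same data.

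Ribosomal protein and nuclear respiratory chain genes were called lower in DLD1 and higher in SW948, and all 4 calls were lost with an estimated correlation (adjusted p = 0.508 and 0.473 in DLD1 and 0.547 and 0.544 in SW948 with an estimated correlation). Much of the size went with a single library. The median log2 fold change was -0.164 in DLD1 without control replicate 1, against -0.40, and 0.09 in SW948 without 2-MiCit replicate 2, against 0.30. Each was its line's library with the steepest length trend, and these transcripts are short. A smaller median without it therefore does not show that the trend is the cause. With the length trends removed the larger adjusted p of the 2 lists was 0.000319 in DLD1 and 0.000448 in SW948 at the preset correlation. That cannot show that the remaining change is real, so how much of the change a length trend accounts for stays open. In DLD1, 1 of 35 splits of the libraries, the real one, gave as large a mean difference of these genes (0.347, highest other 0.325). In SW948, 9 of 35 splits did, so differences between single libraries may account for the change there, and no biological explanation was tested.

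No gene was called in SW948. A single outlying library does not account for it, since 3 genes were called without 2-MiCit replicate 2, nor does depth, since the median library total was 0.963 of that of HCT116. The genes over 2-fold higher in HCT116 had a median log2 fold change of 0.007 in SW948, so a larger spread does not hide changes of that size. A weaker response of SW948 stays as a hypothesis.

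Each line's 8 libraries were also split in the 35 possible ways into 4 and 4. Only the real split, 1 of 35, called as many genes in HCT116 (5124, highest other 3), DLD1 (20, highest other 2) and LoVo (314, highest other 3). The same was true of HT29 (1065, highest other 4), SKCO1 (2776, highest other 4) and SW1417 (984, highest other 4). The smallest share that the real split can reach is 1 of 35, and splits that mix the treatments carry the treatment difference in their spread. By itself the comparison therefore does not exclude chance for these counts. In HCT116, 8 splits part every pair of same-numbered libraries. Among them again only the real one called as many genes, while 3 of those 8, the real one included, called as many lists (highest other 19). In SW948 all 35 splits called at least as many genes as the real 0 (highest other 2). For the gene lists, only the real split called as many in LoVo (13, highest other 12), SW948 (8, highest other 6) and SW1417 (17, highest other 15). This concerns the number of lists, not each list: the real split gave the smallest p of all 35 for 9 of 17 called lists in HCT116, 3 of 11 in DLD1, 6 of 13 in LoVo, 1 of 8 in SW948 (mitosis), 1 of 9 in HT29 (mitosis), 7 of 15 in SKCO1 and 6 of 17 in SW1417. In SW948 as small a p came from 9 splits for nuclear respiratory genes, 16 for mitochondrial genes and 8 for ribosomal proteins, the real one included. Some called lists of other lines did no better. In HCT116 it was 17 splits for mitochondrial genes, 13 for nuclear respiratory genes and 13 for ribosomal proteins. For nuclear respiratory genes in LoVo it was 13, for homologous recombination in HT29 14, and for ribosomal proteins in DLD1 and SKCO1 12 each. As many lists were called by 5 splits in HCT116 (17, highest other 19), 2 in DLD1 (11, highest other 11), 15 in HT29 (9, highest other 14) and 3 in SKCO1 (15, highest other 16), the real one included, so this count does not exclude chance for the number of lists in those lines. In HCT116, DLD1 and SKCO1 each other split that did so kept 3 of the 4 libraries of a treatment together, and so part of the contrast. Splits with 2 libraries of each treatment on both sides called at most 4 lists in HCT116, 6 in DLD1 and 8 in SKCO1, but up to 13 in HT29.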

How the results depend on the processing

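Removal of the length trend, the authors' gene and library factors as offsets, and the counts over at least 4 lines were chosen only after the data were seen. Where a value moved, the cause was not tested.

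DESeq2 gave 324 higher and 150 lower genes in DLD1, 459 and 477 in LoVo, 730 lower in HT29, 4389 and 1454 line-dependent genes in the first and last tables, and 76 higher and 215 lower in at least 4 lines. One fit over a table's lines gave 733 and 619 in DLD1, 120 higher in LoVo, 2 higher in SW948, 1221 and 1270 in HT29, 626 and 1010 in SKCO1, 211 and 227 in SW1417, and 102 lower in at least 4 lines. The replicate block gave 0 higher in DLD1, 1150 and 1034 in HT29, and 1637 and 1566 line-dependent genes. It gave 65 higher and 120 lower in at least 4 lines. The stricter filter gave 40 higher in DLD1. The authors' size factors gave 59 lower in LoVo, and the authors' factors 8 higher and 10 lower in at least 4 lines. Their gene and library factors as offsets gave 299 and 183 in HT29, 434 and 764 in SKCO1, 71 and 127 in SW1417 and 308 line-dependent genes in the last table. With the length trend removed there were 110 and 5 in DLD1, 372 and 296 in LoVo, and 98 lower in at least 4 lines. With an estimated correlation 4 lists were called in HCT116, 0 in DLD1, 0 in LoVo, 0 in SW948, 0 in HT29, 5 in SKCO1 and 1 in SW1417; fry called 0 in SW948.

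Leaving out single libraries, the higher and lower counts ranged over 2041 to 2457 and 1971 to 2630 in HCT116, 1 to 163 and 0 to 20 in DLD1, 32 to 528 and 4 to 540 in LoVo, 0 to 1 and 0 to 2 in SW948, 299 to 594 and 153 to 520 in HT29, 873 to 1264 and 1147 to 1730 in SKCO1, and 187 to 460 and 303 to 670 in SW1417. Called lists ranged over 17 to 19, 10 to 13, 11 to 14, 3 to 8, 7 to 16, 15 to 15 and 15 to 17 in the same order. Line-dependent genes ranged over 1992 to 3679 and 634 to 999, genes in at least 4 lines over 24 to 54 higher and 35 to 117 lower, and in all 7 lines they stayed at 0.

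Of 505 calls of named genes, the one that turned direction was PDE1C in SKCO1, at 0.02 with the authors' gene and library factors as offsets (adjusted p = 0.969). Calls were lost for 131 of 301 with those offsets, 127 with one fit, 40 with the block, 28 without a filter, 21 with the length trend removed, 10 of 204 with the authors' size factors, 7 of 504 with DESeq2, 3 with its size factors, 1 of 487 with the stricter filter, and 144 on leaving out some library. Of 90 list calls, an estimated correlation ended 80, fry 29, leaving out some library 20, length trend removal 7, the block 4 and the stricter filter 2 of 87. Under the block, glycolysis and the tricarboxylic acid cycle in DLD1 (adjusted p = 0.0576 and 0.0557), the ATF4 list in LoVo (0.0661) and histones in SW948 (0.0923) were no longer called; mitochondrial respiratory genes in LoVo (0.0109) and the unfolded protein response and nucleotide synthesis in HT29 (0.0267 and 0.0135) were. Only in HCT116 did all 4 pairs correlate over 0.1 (in HT29 3 did). All 8 libraries correlated best with their own number in HT29, and 6 each in SKCO1, SW1417 and HCT116. Pairing in HT29, SKCO1 and SW1417 stays open. Lists were not recomputed with DESeq2, one fit or the offsets. At the smallest simulated change, the test recovered 2.99% of genes in DLD1, 2.99% in SW948, 28.4% in LoVo and 80.6% in SW1417. How far depth or spread sets this was not tested.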

Other observations

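The genes of the next paragraph, the tubulin set and the tubulin tests were chosen only after values were seen.

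TXNIP rose in HT29 (log2 fold change 1.30), SKCO1 (0.24) and SW1417 (0.31), and ARRDC4 in HCT116 (1.06), HT29 (1.24) and SW1417 (0.22). PDK4 rose in HCT116 (1.00, to 2.77 CPM), LoVo (0.45) and HT29 (0.56). Near-identical aldo-keto reductases, which can share reads, rose too: AKR1C1 in LoVo (0.88), HT29 (0.40) and SW1417 (0.48). AKR1C3 rose in LoVo (0.67), HT29 (0.41), SKCO1 (0.46) and SW1417 (0.62, to 1.32 CPM). The stress cytokine GDF15 rose in HCT116 (1.54) and SKCO1 (0.21). Each gene was uncalled in some tested lines.

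Across 8270 genes the log2 fold changes of HCT116 correlated with those of LoVo (Pearson r = 0.55, and 0.49 with the length trends removed) and of DLD1 (0.51 and 0.42). Those of DLD1 and SW948 ran opposite (-0.68 and -0.51). These 2 lines hold the libraries with the steepest length trends, DLD1 control replicate 1 (-0.424) and SW948 2-MiCit replicate 2 (-0.322), which lie in opposite groups. The correlation without those libraries was not computed, and no gene was called in SW948, so the value does not show opposite responses. All values in this paragraph are correlations across genes, with no library shared between lines.

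Since TUBB, TUBA1B and TUBA1C fell in 4 lines, the hypothesis of a joint fall was tested on the other alpha and beta tubulin genes. Without those 3 genes, the median log2 fold change was below 0 and below that of other tubulin and tubulin folding genes in 6 of 7 lines. It was -0.55 in HCT116 (5 of 6 genes called lower), -0.24 in DLD1 (0 of 6 by edgeR), -0.10 in LoVo (0 of 6), -0.23 in HT29 (1 of 4), -0.18 in SKCO1 (5 of 6) and -0.21 in SW1417 (4 of 6), and 0.03 in SW948 (0 of 5). In LoVo the comparison genes were nearly as low (-0.09), so that line adds little. The median lay within 0.1 of the mitosis median in 3 lines, which leaves open whether the fall is part of that of mitosis genes. Both tests replaced earlier versions that had counted those 3 genes, after their results were seen, and the mitosis test was also made less ready to exclude. These genes share near-identical sequence and possibly reads with those 3, so the test is not independent and single levels are uncertain.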
